A study of Mus musculus with 2 samples.

How the data were processed

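Cells of the mouse cornea and limbus were profiled by droplet single-cell RNA sequencing with the 10x Genomics protocol. Per the labels, 1 wild-type and 1 Becn1 heterozygous female littermate of 28 days were used, the lens, retina, iris and trabecular meshwork were removed, and most of the conjunctiva was dissected away before collagenase and trypsin digestion. Each genotype was therefore represented by 1 animal and 1 library, and genotype, animal and library preparation cannot be separated.

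The deposited values were UMI counts per gene and cell barcode, whole numbers with no normalization, for 27998 features. Per the submitters' processing notes, the counts were made with Cell Ranger 2.1.1 on the mm10 build. The step that called cell barcodes, and the annotation release used for counting, are not given in the sources used here. The deposited matrices held 2513 barcodes with 54913980 UMIs in the wild-type library and 5155 barcodes with 74363359 UMIs in the heterozygote library. The lowest barcode had 8089 UMIs in the wild-type library and 5430 in the heterozygote library, so the libraries entered the analysis with different lower limits of RNA content. Median depth was 16967 UMIs and 3097 genes per barcode in the wild-type library, and 11571 UMIs and 2515 genes in the heterozygote library. The median share of mitochondrial UMIs was 1.79% and 1.75%. Gene positions were looked up by Ensembl identifier in a GENCODE annotation of the same assembly, which held 27722 of the features.

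Cells with at least 500 genes and at most 20% mitochondrial UMIs were to be kept, and no deposited barcode failed these limits. Doublet scores were computed per library with Scrublet as implemented in scanpy 1.11.5, and the highest-scoring barcodes were removed at a rate of 0.8% per 1000 barcodes. This removed 51 barcodes (2.03%) from the wild-type and 213 (4.13%) from the heterozygote library and left 2462 and 4942 cells. Counts of both libraries were log-normalized together, 2000 variable genes were reduced to 30 principal components, and cells were grouped by the Leiden algorithm (leidenalg 0.10.2) with 15 neighbours at resolution 1.0. Genes of the 23 lists described below, mitochondrial genes and ribosomal protein genes were kept out of the variable genes, so that they did not define the clusters directly. Other genes that vary with them stayed in, so the lists are not independent of the clusters. Corneal clusters 6 and 18 were led by cell cycle genes such as Ube2c and Cdc20. No integration of the libraries was applied. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.

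The 26 clusters were named from sets of marker genes. The class with the highest mean standardized log2(CPM + 10) over its markers was taken, at least 3 markers had to reach 20 CPM, and epithelial clusters were compared with one another only. Goblet cell and trabecular or ciliary markers were left out of these scores. A cluster stayed unnamed when its best class led the next by less than 0.1, or when its 10 genes of highest fold held more markers of other classes than of its own. For this last condition the goblet cell and trabecular or ciliary markers did count as markers of other classes. The scoring rule and the margin of 0.1 were settled after the clusters' markers had been seen, over several versions, and the condition on the 10 top genes was added after ratios between the libraries had been seen. That condition took cluster 10 (85 wild-type and 258 heterozygote cells, 3.45% and 5.22% of cells) out of the superficial class and cluster 20 (10 and 105 cells, 0.406% and 2.13%) out of the stromal class. In cluster 20 the only marker of another class was Mgp, from the trabecular or ciliary set, and no stromal marker was among the top genes. The margin kept out the epithelial clusters 8 (4.22% and 6.11%), 11 (3.57% and 3.82%) and 16 (2.88% and 1.96%) and the stromal cluster 19 (2.19% and 1.60%). Clusters 11 and 16 failed the condition on the 10 top genes as well, so they would stay unnamed without the margin. Mast cell transcripts such as Mcpt4, Tpsb2 and Cma1 were among the top genes of cluster 11, and the collagens Col1a1 and Col1a2 with Dcn led cluster 16. All epithelial clusters, named or not, entered the sums called whole epithelium.

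Raw counts were summed per library and class and scaled to CPM by the library's UMIs in that class. Ratios are log2 of the heterozygote over the wild-type CPM, or of the limbal over the corneal CPM, with 0.5 added to each count. Intervals of ratios are exact conditional (Clopper-Pearson) 95% intervals, those of levels are exact Poisson and those of cell shares exact binomial. All of them cover counting error only and leave out the variation between animals, which 1 library per genotype cannot give. No p-value and no number of changed genes is reported for this reason. Ratios over many genes were described for genes with a mean of at least 20 CPM.

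Gene lists covered autophagy, lysosome, dissociation and immediate early genes, heat shock, S phase, G2 and M phase, cell cycle inhibitors and p53 targets, oxidative stress, metallothioneins, the unfolded protein response, the interferon response, antigen presentation, epithelial alarm and innate immunity, the cornified envelope, glycolysis and hypoxia, cholesterol synthesis, nuclear and mitochondrial genes of oxidative phosphorylation, the cytoplasmic ribosome, YAP and TEAD targets, Wnt and Notch signalling, adhesion and basement membrane, and corneal epithelial transcription factors. For each list the median log2 ratio of its measured members is given with an order-statistic interval over the members, which for fewer than 6 members spans their whole range, and with its percentile among 10000 random lists of the same size matched on mean expression. Genes of the random lists were drawn independently, whereas members of a list may vary together. A shared shift, also one in the mix of cells, can therefore place a list beyond all random lists, and the percentile is descriptive only. The lists, cell type markers, filters, comparisons, processing alternatives other than those named as chosen later, and the rule for named genes were fixed before the data were examined.

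Genes named between the libraries were the 12 highest and 12 lowest ratios among genes with a mean of at least 50 CPM in the epithelium. Predicted genes were left out, the level outside the epithelium could not exceed that within it, and the ratio had to lie on the same side of 0 in every epithelial class with at least 50 cells in both libraries. In the stroma the 4 highest and 4 lowest ratios were taken at a mean of at least 100 CPM and with a stromal level above the epithelial one. The 4 members of largest absolute ratio were taken per list, for the limbal comparison among members of equal direction in both libraries. Not every gene these rules took is printed. Cycling cells were those with at least 5 UMIs over the G2 and M phase genes after each cell had been thinned to 4000 UMIs, which left out no cell.

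The calculation of ratios, intervals and list percentiles was tested on simulated counts of 4485 genes, 200 of them with known changes. The counts were independent Poisson draws from the summed levels and depths of the libraries. Clustering, naming, thinning, variation between animals and genes that vary together were not simulated. The interval held the true ratio for 95.07% of the genes, which checks the calculation only, since the draws follow the model the interval assumes. A true log2 ratio of 1.0 came back as a median of 0.999 and one of 0.5 as 0.497. A simulated list of 15 changed genes lay above all random lists, and a list of 15 unchanged genes lay at percentile 6.39. Alternatives covered the cell filters, doublet removal, clustering resolution, list genes among the variable genes, centring each library, scaling (including TMM factors from edgeR 4.0.16 in R 4.3.3), weighting of classes, depth, expression limits and the cycling threshold. Free RNA was present in both libraries: Krt12, a keratin of corneal epithelium, was counted at 836 CPM in the wild-type and 1228 CPM in the heterozygote stromal class, against 24235 and 23721 CPM in the corneal class.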

Results

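The study measured gene expression in single cells of the mouse cornea and limbal rim, the border zone where the stem and early transit amplifying cells of the corneal epithelium are thought to reside. It compared a wild-type mouse with a littermate carrying a single functional copy of Becn1, which encodes beclin 1, a component of the lipid kinase complex that starts autophagosome formation. There was 1 library per genotype, so no difference between the genotypes has a replicate check and every interval covers counting error only. After doublet removal 2462 wild-type and 4942 Becn1 heterozygote cells remained, of which 1869 and 3493 were epithelial. The epithelial cells held 46038507 UMIs in the wild-type and 56580742 UMIs in the heterozygote library.

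The cells fell into 26 clusters, 15 of them epithelial. Limbal basal-like cells, in clusters 12, 17 and 23, had high Gpha2, Krt15, Ifitm3 and Cd63 and numbered 183 in the wild-type and 290 in the heterozygote library. Gpha2, a glycoprotein hormone subunit and limbal marker (chromosome 19, 6226380 to 6227768), reached 2141 CPM in wild-type and 2072 CPM in heterozygote limbal cells, against 84.0 and 89.5 CPM in corneal cells. Corneal epithelial-like cells, in 6 clusters, had high Krt12 and Aldh3a1 and numbered 1167 and 1971. Superficial-like cells (102 and 245) had high Psca and Upk1b, and conjunctival-like cells (69 and 141) had high Krt4, Krt13 and Krt19. Keratocyte or stromal fibroblast-like cells (496 and 1163) had high Dcn, Lum and Col1a1. Immune and stress genes were among the leading genes of several named clusters, Lcn2, Cxcl1, Cxcl2, Csf3 and S100a8 in limbal cluster 12, Nr4a1, Fos and Atf3 in limbal cluster 23, Socs3 and Fos in corneal cluster 5, and Klf2 and Nr4a1 in stromal cluster 3.

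**Figure D1:**
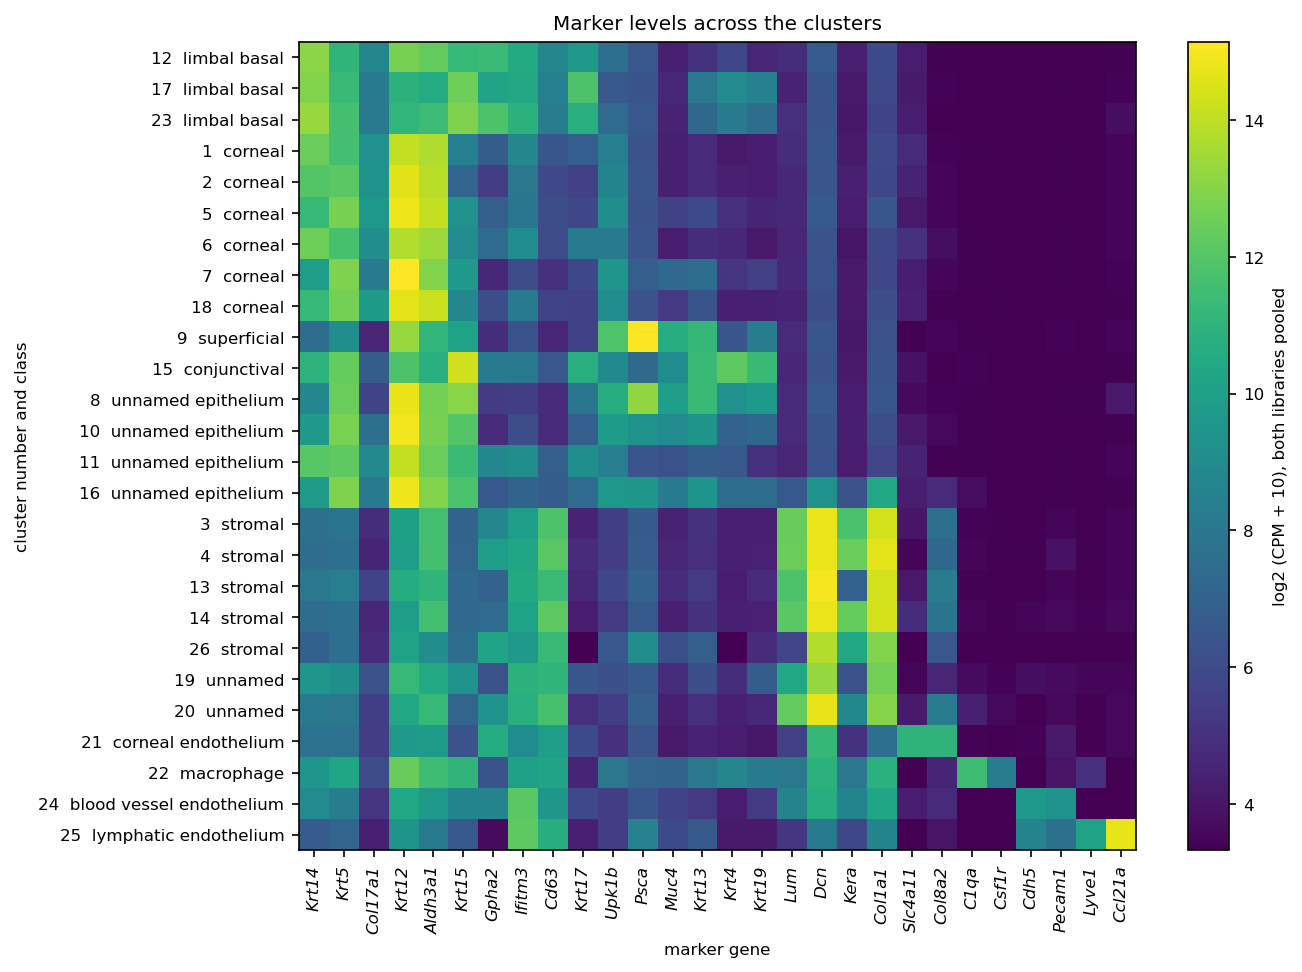
Heat map of the level of 28 marker genes (horizontal axis, log2 of CPM plus 10, colour scale) in the 26 clusters (vertical axis) with both libraries pooled. Gpha2 is high in the 3 limbal basal-like clusters and is also seen in stromal clusters and corneal endothelium, while Krt12 is high in the corneal clusters and in some unnamed epithelial ones.

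Becn1, the targeted gene (chromosome 11, 101285952 to 101302286, minus strand), was read at almost equal levels in both libraries. In whole epithelium it was counted at 44.4 CPM in the wild-type library (95% Poisson interval 42.5 to 46.4, from 2046 UMIs) and at 44.9 CPM in the heterozygote library (43.1 to 46.7, from 2539 UMIs). The log2 ratio was 0.01 (-0.07 to 0.10). In stromal cells the levels were 29.0 and 34.6 CPM, a log2 ratio of 0.25 (-0.01 to 0.52). The labels do not say which part of the gene is missing, and a tag at the 3′ end may be read from both alleles, so this level does not check the genotype. With TMM scaling the epithelial ratio was 0.13.

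The next comparison asked which epithelial transcripts differed between the heterozygote and the wild-type library. The 12 highest genes taken in the heterozygote library were led by S100a9 and Isg15. S100a9, a calcium-binding alarm protein, was counted at 104.0 CPM in the wild-type and 209 CPM in the heterozygote epithelium, a log2 ratio of 1.01 (0.96 to 1.06). Isg15, an interferon-induced ubiquitin-like protein, had 97.2 and 195 CPM, a log2 ratio of 1.00 (0.96 to 1.06). The cornified envelope gene Lce3a (0.88), the alcohol dehydrogenase Adh6a (0.87), Plekhs1 (0.70) and the serine protease Prss27 (0.70) followed. The rule also named Serpinb11 (0.65), Gda (0.64), Plac8 (0.63), Cysrt1 (0.57), AA467197 (0.52) and the interferon-inducible Ifitm1 (0.46).

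Several of these transcripts were concentrated in superficial-like cells. Isg15 was counted there at 1253 CPM in the wild-type and 1904 CPM in the heterozygote library, against 15.05 and 20.5 CPM in corneal cells, and Lce3a had 6885 and 9447 CPM against 10.7 and 14.8 CPM. Within superficial-like cells the log2 ratio was 0.51 for S100a9, 0.60 for Isg15 and 0.46 for Lce3a. Within corneal cells it was 1.45 for S100a9, 0.45 for Isg15 and 0.47 for Lce3a. Superficial-like cells made up 5.46% of the wild-type and 7.01% of the heterozygote epithelium. With the 4 named epithelial classes weighted equally the ratio was 0.59 for Isg15, 0.40 for Gda and 0.18 for Ifitm1, and with clusters weighted equally, an alternative chosen after seeing the data, it was 0.30 for Lce3a and 0.36 for Cysrt1.

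Several ribosomal protein genes were among the lowest in the heterozygote library. Rps28 (chromosome 17, 33819027 to 33824562) was counted at 2669 CPM in the wild-type and 1709 CPM in the heterozygote epithelium, a log2 ratio of -0.64 (-0.66 to -0.63). Rps27rt (-0.79), Rps27 (-0.55), Rps29 (-0.54), Rpl35 (-0.48), Rps21 (-0.46), Rpl6l (-0.45) and Rpl38 (-0.45) were lower as well. Rps27rt is a near copy of Rps27, and Rpl6l, annotated as a processed pseudogene, of Rpl6, so the split of reads between copies is uncertain. The other genes named at this end were the transcription factor Dmrta2 (-0.66), the hexokinase Hk2 (-0.56) and Wdr89 (-0.47), and Dmrta2 had -0.33 with clusters weighted equally. The same ribosomal genes were also lower in stromal cells, by log2 ratios of -0.41 for Rps28, -0.31 for Rps27 and -0.34 for Rps29. In stromal cells the list of 39 cytoplasmic ribosome genes had a median of 0.12, with 29 genes higher and 10 lower.

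**Figure D2:**
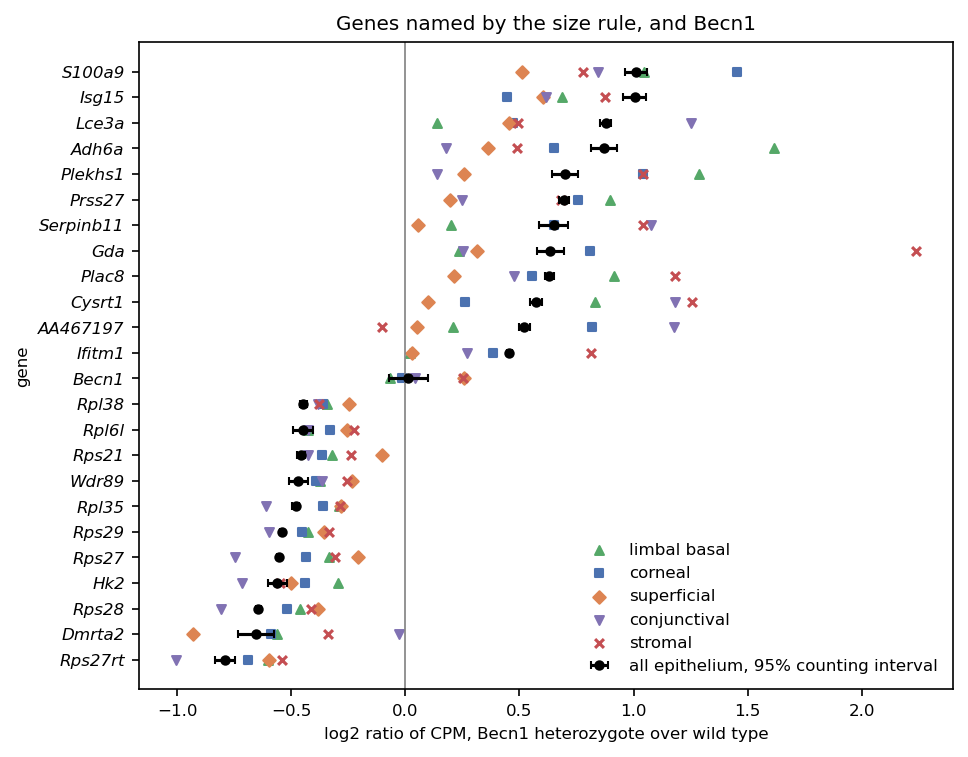
Log2 ratio of CPM, Becn1 heterozygote over wild type (horizontal axis), for 12 of the highest and 11 of the lowest genes and Becn1 (vertical axis), in whole epithelium (black points, 95% counting interval) and in each class (coloured symbols). S100a9 and Isg15 lie near 1, Rps27rt at -0.79 and Becn1 near 0.

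Over the 4218 genes measured in the epithelium, the central 90% of log2 ratios ran from -0.32 to 0.25 with a median of -0.04. Counting error alone gave -0.07 to 0.07, so the libraries differed by more than counting error over genes in general. Without replicates the part of this spread that comes from the animals or the preparation cannot be given. TMM scaling raised every ratio by 0.12 and the median of all genes to 0.07, so a gene or list with a ratio between -0.12 and 0 has the opposite sign under that scaling.

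Of the gene lists, the interferon and alarm lists were highest with pooled cells. The interferon response list had a median log2 ratio of 0.37 (0.03 to 1.00), above all but a few of 10000 matched random lists (percentile 99.99), and 8 of its 9 measured genes were higher in the heterozygote epithelium. Ifit1 (1.19), Irf7 (0.45) and Ifi27 (0.39) were examples besides Isg15. The epithelial alarm and innate immunity list had a median of 0.28 (0.01 to 0.44, percentile 100) with 10 of 11 genes higher, among them Slpi (0.44), an inhibitor of leukocyte proteases, the cytokine Il18 (0.36) and the stress keratin Krt6b (0.31). With the 4 named epithelial classes weighted equally the medians were 0.24 for the interferon and 0.11 for the alarm list, below 0.34 for the cholesterol synthesis list. Slpi and Krt6b were not higher within superficial-like or conjunctival-like cells, where Slpi had log2 ratios of -0.70 and -0.76.

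Wnt and Notch signalling and immediate early genes were lower in the pooled heterozygote epithelium. The Wnt and Notch signalling list had a median of -0.33 (-0.44 to -0.06), below all 10000 random lists, with 11 of 13 genes lower. The Notch ligands Dll1 (-0.67) and Jag1 (-0.44) and the receptors Notch3 (-0.47) and Notch1 (-0.41) were its largest members. In limbal cells the list had a median of 0.11 (-0.46 to 0.18) with 6 of 10 genes higher. The median was -0.06 when only genes of at least 100 CPM were used and -0.17 with clusters weighted equally. The dissociation and immediate early list, which is known to respond to tissue digestion, had a median of -0.14 (-0.38 to -0.09), also below all random lists, with 27 of 31 genes lower. Klf2 (-0.66), Fosb (-0.64), Nr4a1 (-0.59) and Cyr61 (-0.52) led it, and the median was -0.03 with TMM scaling and -0.05 with clusters weighted equally.

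Mitochondrially encoded genes had a median of -0.18 (-0.62 to -0.06, percentile 0.175) with 11 of 11 genes lower, and the short mt-Nd3 (-0.83) and mt-Nd4l (-0.62) stood below mt-Nd2 (-0.22) and mt-Nd1 (-0.21). With TMM scaling this median was -0.06. Cholesterol synthesis genes had a median of 0.08 (0.02 to 0.20, percentile 99.74) with 14 of 18 genes higher, led by Pmvk (0.57), Nsdhl (0.46) and Mvd (0.36), enzymes of the mevalonate and sterol pathway. That median was 0.34 with the classes weighted equally, and the log2 ratios of Pmvk, Nsdhl and Mvd were 1.73, 1.20 and 1.83 in conjunctival-like cells.

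Autophagy genes, the process in which beclin 1 acts, showed no common direction. The list median was -0.04 (-0.09 to 0.06, percentile 51.89), 9 of 19 genes were higher and 10 lower, and the median was 0.08 with TMM scaling. Map1lc3b (0.23) and Gabarapl2 (0.20), which encode ubiquitin-like proteins of the autophagosome membrane, were higher, and the protease Atg4d (-0.21) and Nrbf2 (-0.14) were lower. Lysosomal genes had a median of -0.05 (percentile 30.79), with Psap at -0.22, Asah1 at -0.20 and Ctsh at 0.18.

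The other lists had medians between -0.22 and 0.12. They were 0.12 for antigen presentation (H2-D1 0.17, B2m 0.15), 0.04 for the unfolded protein response (Chac1 0.31, Trib3 0.25), 0.02 for nuclear genes of oxidative phosphorylation (Cox5a 0.26, Sdhd -0.33) and -0.02 for YAP and TEAD targets (Nuak2 -0.56, F3 -0.39). The antigen presentation median had the same sign in 1 of the 4 named epithelial classes, and was -0.24 in limbal cells with 4 of 4 genes lower. The cornified envelope list had -0.03 (Ppl 0.21) and the cytoplasmic ribosome list -0.04 over 39 genes. No named epithelial class shared the sign of this pooled ribosome median. The ribosome list had a median of 0.09 in limbal cells (26 of 39 genes higher) and 0.06 in corneal cells (28 of 39 higher). Glycolysis and hypoxia genes had -0.06 (Hk2 -0.56, Eno1 -0.40). Heat shock genes had -0.07, where Hspa1a (-0.41) and Hspa1b (-0.53) are near-identical copies. Oxidative stress genes had -0.08, although the ferritin heavy chain Fth1 (0.60) and the glutathione transferase Gsto1 (0.43) were higher. G2 and M phase genes had -0.08 (Hmgb2 -0.34), S phase genes -0.09 (Rrm2 -0.42), and adhesion and basement membrane genes -0.09 (Itga3 -0.25). The G2 and M phase median differed in sign between classes, with 0.06 in corneal cells (14 of 20 genes higher) and -0.23 in limbal cells (11 of 14 lower). Corneal epithelial transcription factors had -0.09, with Pax6, a regulator of eye development, at -0.65 and Sox9 at -0.33. Pax6 was concentrated in corneal clusters 5 and 18, which held 9.83% and 2.84% of wild-type and 5.30% and 1.497% of heterozygote cells. Cell cycle inhibitors and p53 targets had -0.11 (Cdkn2b 0.31, Mdm2 -0.25), and the metallothioneins Mt1 and Mt2 had -0.21 and -0.23.

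In stromal cells, Apoe, which encodes a lipid carrier, was higher in the heterozygote library at 3165 CPM against 1960 CPM, a log2 ratio of 0.69 (0.66 to 0.72). Fjx1 (0.54), the translation repressor Eif4ebp1 (0.47) and the stress-inducible Nupr1 (0.47) were higher too. Tnmd (-0.75), Igfbp5 (-0.63), Dlk1 (-0.58) and the orphan nuclear receptor Nr4a2 (-0.52) were lower. The libraries divided differently over the stromal clusters: cluster 14, with Apoe and Fjx1 among its leading genes, held 48 of 496 wild-type and 170 of 1163 heterozygote stromal cells, and cluster 26, with Tnmd among its leading genes, held 8 and 5. Immediate early genes had a median of -0.35 in stromal cells, with 31 of 33 lower. The mix of clusters enters this median, and its part was not tested. The immediate early gene Fos had 4603, 3081 and 5349 CPM in clusters 3, 13 and 26, against 171 and 196 CPM in clusters 4 and 14. Clusters 3 and 13 held 200 and 86 wild-type and 419 and 167 heterozygote cells. Clusters 4 and 14 held 154 and 48 wild-type and 402 and 170 heterozygote cells. Over 4538 genes the central 90% of stromal ratios ran from -0.34 to 0.27, and the ratio of Igfbp5 lay between -0.85 and -0.22 over 11 alternatives.

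The limbal comparison asked what sets limbal basal-like cells apart from other corneal epithelial cells, within each library. Cholesterol synthesis genes were lower in limbal cells. The list median was -1.81 (-2.25 to -1.33) in the wild-type and -1.23 (-1.59 to -0.93) in the heterozygote library, below all random lists in both, and 15 of 15 genes were at least 1.5 times lower in both libraries. Fdps, the farnesyl diphosphate synthase (chromosome 3, 89093588 to 89101959), was counted at 40.5 CPM in limbal and 256 CPM in corneal wild-type cells, a log2 ratio of -2.65 (-2.93 to -2.40), and the heterozygote ratio was -1.62. Insig1 (-2.44 and -1.59) and Mvk (-2.25 and -1.84) went the same way. The medians were as small as -1.08 and -0.62 under other clusterings.

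Alarm and innate immunity genes were higher in limbal cells, with list medians of 1.80 (0.31 to 2.36) and 1.46 (0.15 to 1.87), above all random lists, and 10 of 12 genes higher in both libraries. Lcn2, the iron-scavenging lipocalin 2 (chromosome 2, 32384633 to 32388252), was counted at 106 CPM in limbal and 1.21 CPM in corneal wild-type cells, a log2 ratio of 6.42 (5.92 to 7.02), and at 140.0 and 6.84 CPM in the heterozygote library, a ratio of 4.35. The chemokine Ccl20 (2.74 and 1.87), Slpi (2.36 and 1.30) and S100a8 (1.35 and 2.73) were higher as well. The interferon response list gave no clear direction, with medians of -0.57 (-1.74 to 0.38) and -0.60 (-2.06 to 0.34) over 5 measured genes, of which 3 were lower and 1 was higher in both libraries.

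Lysosomal genes were lower in limbal cells, with medians of -0.43 and -0.28 (percentiles 0.13 and 1.22) and 16 of 23 genes lower in both libraries. The protease Lgmn was lower (-1.72 and -1.13), whereas the cathepsin Ctsz was higher (2.08 and 1.77). With list genes kept among the variable genes the lysosomal medians were -0.13 and -0.14. Autophagy genes had medians of 0.01 in both libraries, with Map1lc3a (0.97 and 0.93) and Atg101 (0.87 and 0.85) higher and the mitophagy receptor Bnip3l (-1.02 and -0.97) lower. G2 and M phase genes had medians of -0.38 and -0.80 with 13 of 15 genes lower in both libraries, including Ube2c (-0.86 and -1.58) and Birc5 (-1.03 and -1.37). These medians ranged from -0.16 to -1.77 in the wild-type and from -0.32 to -1.88 in the heterozygote library over the alternatives, most of which regroup the cells.

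Genes of other lists also had large limbal ratios. Among transcription factors the BMP-responsive Id1 (1.75 and 1.80) and Id3 (1.09 and 1.25) were higher and Pax6 (-1.48 and -0.82) was lower in limbal cells. The Pax6 level of limbal clusters 12 and 17 was near that of corneal clusters 1, 2 and 6, and its ratio was as small as -0.38 and -0.31 over the alternatives. The small heat shock protein gene Hspb8 was higher by 4.53 and 3.74, and Wnt10a by 1.16 and 1.61, while Notch3 (-1.65 and -1.28) and the Notch target Nrarp (-1.75 and -1.42) were lower. The glutathione transferase Gsta4 was lower (-2.17 and -2.06) and Gstm1 higher (1.68 and 1.67). In the cornified envelope list Dmkn (2.84 and 1.89) was higher and Evpl (-2.36 and -2.26) lower. Such ratios moved with the grouping of cells, to -0.85 and -0.80 for Gsta4, -1.07 and -0.83 for Evpl and -0.61 and -0.82 for Lgmn at the smallest. Across 4279 genes the limbal over corneal ratios of the 2 libraries correlated with Pearson's r of 0.938, where genes are not independent replicates.

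**Figure D3:**
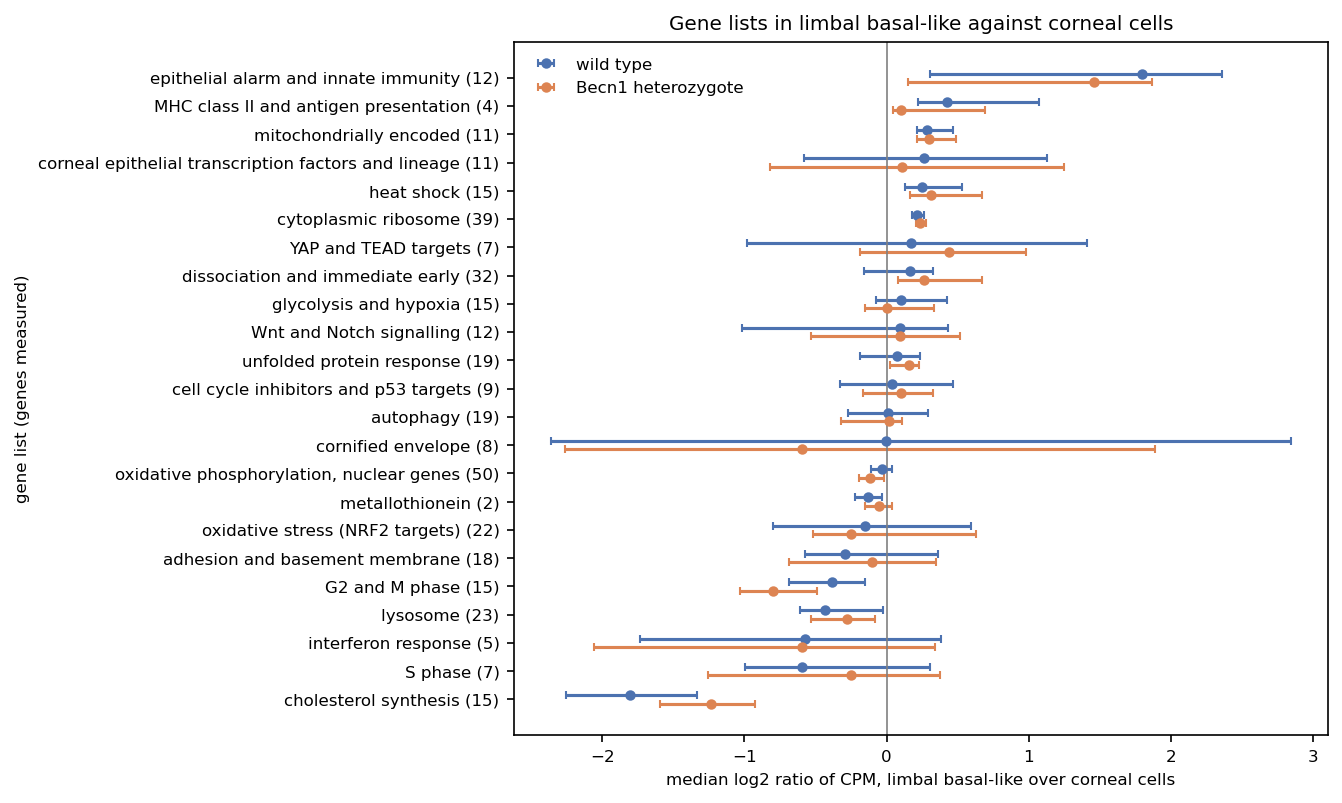
Median log2 ratio of CPM in limbal basal-like over corneal cells (horizontal axis) for 23 gene lists (vertical axis, number of measured genes in brackets) in the wild-type and heterozygote libraries, with order-statistic 95% intervals over the genes of a list. The alarm list is highest at 1.80 and 1.46 and the cholesterol synthesis list lowest at -1.81 and -1.23.

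Cycling cells were counted in the limbal, corneal, superficial, conjunctival and stromal classes. After thinning to 4000 UMIs, 24.6% of wild-type limbal cells (95% binomial interval 18.5 to 31.5) and 18.6% of heterozygote limbal cells (14.3 to 23.6) had at least 5 UMIs of G2 and M phase genes. The limbal shares rest on a different mix of clusters: Top2a was at 62.3 CPM in cluster 17 and 2.58 CPM in cluster 12, and cluster 17 held 77 of 183 wild-type and 83 of 290 heterozygote limbal cells. In corneal cells the shares were 27.2% (24.7 to 29.9) and 27.8% (25.8 to 29.8). Stromal cells, as background, had 0.806% and 0.774%, and no superficial-like cell reached the limit (0 of 102 and 0 of 245). Conjunctival-like cells had 7.25% and 2.13%. Without thinning the limbal shares were 82.5% and 58.3%, the corneal ones 82.9% and 67.2% and the stromal ones 14.1% and 6.79%, at median depths of 13881 and 9675 UMIs in limbal, 18391 and 12377 in corneal and 11940.5 and 8229 in stromal cells. The gap between limbal and corneal shares depended on the grouping: with at most 10% mitochondrial UMIs the shares were 17.4% in limbal and 36.1% in corneal wild-type cells, and with at least 1000 genes they were 13.8% and 37.8% in the heterozygote library.

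Shares of cells were counted in each library, and no direction is read for any class. Limbal basal-like cells made up 7.43% (6.43 to 8.54) of wild-type and 5.87% (5.23 to 6.56) of heterozygote cells, a ratio of heterozygote to wild-type share of 0.789 (0.660 to 0.944). This ratio lay between 0.743 and 0.949 over 10 alternatives. Corneal cells made up 47.4% and 39.9% (ratio 0.841, 0.797 to 0.888), and stromal cells 20.1% and 23.5% (ratio 1.17, 1.06 to 1.28). Conjunctival-like cells were 2.80% and 2.85%, superficial-like cells 4.14% and 4.96%, and unnamed epithelial clusters 14.1% and 17.1%. Lce3a, Plekhs1, AA467197 and Isg15 both lead the superficial-like cluster and differ between the libraries. Shares of single dissections depend on the tissue left on the rim and on the barcode limits of 8089 and 5430 UMIs, which lie close to the depth of stromal cells.

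**Figure D4:**
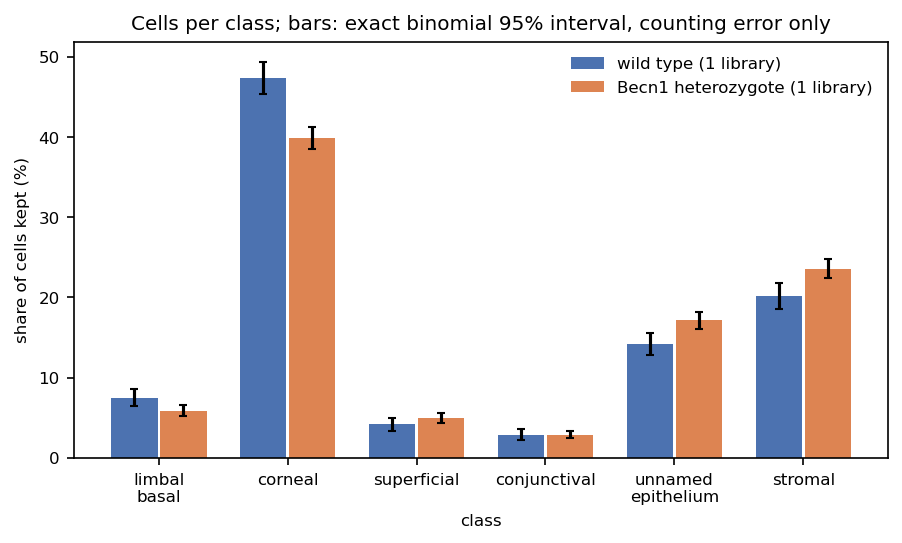
Share of the cells kept (vertical axis, percent) in each class (horizontal axis) for the wild-type and the heterozygote library, with exact binomial 95% intervals for counting error only. Corneal cells are 47.4% and 39.9%, and limbal basal-like cells 7.43% and 5.87%.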

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

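Of the tests in this part, those of ribosomal and mitochondrial messages in the stroma, of the summed copies and of free RNA for the interferon and alarm lists were chosen only after the result was seen, and the other tests were written before their result. A free RNA test that set S100a9 against Isg15 alone was replaced because single top genes exclude nothing.

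Populations outside the comparisons were flagged because their cells form separate clusters that none of them used. A corneal endothelium-like cluster of 47 cells (11 wild-type and 36 heterozygote) had Slc4a11 at 1969 and 2101 CPM, Car3 at 9141 and 8257 CPM and Npy, which encodes a neuropeptide, at 8441 and 7671 CPM. A macrophage-like cluster of 40 cells (9 and 31) had Cd74, the invariant chain of antigen presentation, at 26392 and 14388.5 CPM. Its heterozygote cells also held epithelial RNA, which lowers the Cd74 share. Krt12 had 998 and 6796 CPM and Krt15 103 and 2811 CPM in this cluster, against 1228 and 168 CPM in heterozygote stromal cells. A blood vessel endothelium-like cluster of 27 cells (7 and 20) had Fabp4 at 1280 and 1940 CPM and Plvap at 960 and 1112 CPM. A lymphatic endothelium-like cluster of 21 cells (6 and 15) had the chemokine Ccl21a at 34017 and 21618 CPM. These numbers are too small for a comparison of the genotypes.

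The first pattern is the lower level of 9 ribosomal protein genes or copies of such genes (Rpl6l is annotated as a processed pseudogene), mt-Nd3 and mt-Nd4l in the heterozygote library, with a median log2 ratio of -0.54 in the epithelium. A different mix of epithelial cells is argued against as the whole source. The same 11 genes had a median of -0.31 (-0.52 to -0.23) in stromal cells. That fall was smaller than the epithelial one, so a part from the mix stays open. Reads shared between copies stay open: the summed counts of Rps27 and Rps27rt had a ratio of -0.57 (-0.58 to -0.56), but both genes were lower singly, so the sum had to be lower too, and Rpl6l was not tested. A loss of short messages in the library stays open: 37 other genes with messages under 600 nucleotides lay -0.016 (-0.19 to 0.05) from 4071 longer genes, an interval that reaches the size a loss would need, and in stromal cells such genes lay -0.10 (-0.22 to -0.02) from longer ones, while the annotated lengths describe several of the 11 genes poorly. Genotype, animal and preparation cannot be told apart here, and each may be the source.

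The second pattern is the higher level of interferon and alarm genes in the heterozygote epithelium, with medians of 0.37 and 0.28. A larger share of superficial cells could contribute: with the 4 named classes weighted equally the medians were 0.24 (-0.06 to 0.44) and 0.11 (-0.04 to 0.31), intervals too wide to decide. The unnamed clusters enter the pooled medians only, and made up 18.6% of wild-type and 24.2% of heterozygote epithelium. Among them cluster 8 (4.22% and 6.11% of cells) had Isg15 at 138 CPM and Ifit3 among its leading genes. Its part was not tested. Free RNA, estimated from Krt12 in stromal cells at 3.86% of the epithelial level in the wild-type and 5.74% in the heterozygote library, stays open for the interferon genes within corneal cells: their median was 0.21 (-0.36 to 0.30) before and 0.080 (-0.43 to 0.27) after its subtraction, and the interval of 5 genes reached below 0 already before. For the alarm genes it is argued against as the whole source, since their median in corneal cells was 0.38 before and 0.36 (0.06 to 1.19) after subtraction. Genotype, and a difference between these animals in exposure or surface inflammation, stay open and were not tested.

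The third pattern is the higher level of cholesterol synthesis genes in heterozygote limbal cells, where 12 of 12 measured genes were higher with a median log2 ratio of 0.50 (0.33 to 0.75), against -0.01 in corneal cells. Over the alternatives this limbal median lay within that interval in 9 and outside it in 1. The rise was not limited to limbal cells, since Pmvk, Nsdhl and Mvd were also higher in conjunctival-like cells. With the named epithelial classes weighted equally the list median was 0.34. In superficial-like cells the list went the other way, with a median of -0.35. Free corneal RNA, at 3.45% and 5.18% of the corneal level, is argued against, since subtracting it left 0.49 (0.32 to 0.79). A different mix of limbal clusters stays open: the lower of the medians within the larger clusters was 0.39 (0.19 to 0.65) in cluster 12, and cluster 17 had 0.70. More corneal-like cells within the class stay open too, with 0.45 (0.19 to 0.63) among 153 wild-type and 235 heterozygote limbal cells with at least 2 Gpha2 UMIs. A part from conjunctival-like cells within the limbal class was not tested. Krt4, which was high in conjunctival-like cells, had 508 CPM in cluster 17 and 47.7 CPM in cluster 12. Reduced Becn1 dosage may also be the source, which 1 animal per genotype cannot test, and the difference between limbal and corneal cells was not tested.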

How the results depend on the processing

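No paired analysis was possible because each genotype had 1 library. The naming of clusters without a minimum lead, the clustering without cell-cycle-linked genes, the equal weighting of clusters and the addition of unnamed stromal clusters were chosen after seeing the data. Removing the filters on genes and mitochondrial share left out no cell and so tests nothing, although it is counted among the alternatives. The grouping of cells was unstable: asking for at least 1000 genes left out 2 cells and asking for at most 10% mitochondrial UMIs left out 6, yet wild-type corneal cells numbered 762 and 717 after these steps, against 1167. The 24 genes taken by rule in the epithelium kept their direction in all 15 alternatives run, and so did the 8 stromal genes in 11. For the 24 genes this was partly fixed by the rule, which took extreme ratios with the same sign in every class. Equal weighting of classes could therefore not turn them, and the TMM shift of 0.12 was smaller than each of their ratios. The interferon median lay between 0.24 and 0.49, the alarm median between 0.11 and 0.40 and the Wnt and Notch median between -0.36 and -0.06, with 1 sign each over 17 alternatives. In limbal against corneal cells the alarm medians lay between 1.29 and 1.95 in the wild-type and between 0.99 and 1.51 in the heterozygote library, and the lysosomal, interferon and cholesterol medians stayed below 0 in 15 alternatives. Ratios of class shares stayed within the counting intervals of the values in the report in 49 of 50 cases, the exception being limbal cells at 0.949 with at most 10% mitochondrial UMIs. The cholesterol median between the libraries in limbal cells lay between 0.25 and 0.72. The heterozygote library was shallower and the smallest class compared held 69 wild-type cells. The cause was not tested for any difference listed next, unless stated.

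With TMM scaling, which shifts all genes alike by construction, the log2 ratio of Becn1 was 0.13 and the medians were 0.076 for autophagy, -0.028 for immediate early and -0.060 for mitochondrially encoded genes. With classes weighted equally the cholesterol median in the epithelium was 0.34. With clusters weighted equally the immediate early median was -0.051 and the width of the central 90% of ratios 0.46, against 0.57 with pooled cells. A limit of at least 5 CPM gave a width of 0.62, and one of at least 100 CPM an autophagy median of 0.080 and a heterozygote limbal G2 and M phase median of -0.32.

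The limbal over corneal median of G2 and M phase genes in the wild-type and heterozygote libraries was -1.62 and -1.84 with at least 1000 genes per cell, -1.77 and -1.88 with at most 10% mitochondrial UMIs, and -1.08 and -1.34 without doublet removal. It was -1.50 and -1.85 at resolution 0.5, -0.69 and -1.32 at resolution 1.5, -1.36 and -1.68 with list genes kept, and -0.73 and -1.24 with each library centred. Against corneal basal-like cells only it was -1.15 and -1.33, and without cell-cycle-linked genes the heterozygote median was -0.37. The heterozygote cholesterol median was -0.62 with at least 1000 genes, -0.69 with at most 10% mitochondrial UMIs, -0.72 at resolution 0.5, -0.90 at resolution 1.5, -0.89 with centring, -0.72 without cell-cycle-linked genes and -0.78 with list genes kept, where the wild-type median was -1.08.

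Cycling shares moved with the threshold and depth by construction. For wild-type and heterozygote limbal cells and then corneal cells they were 45.9%, 40.7%, 45.6% and 44.5% with at least 3 UMIs, and 10.9%, 7.59%, 17.5% and 17.7% with at least 10 UMIs. They were 10.4%, 8.28%, 18.4% and 18.2% after thinning to 2000 UMIs, and 82.5%, 58.3%, 82.9% and 67.2% without thinning. Corneal shares in the wild-type and heterozygote libraries were 34.9% and 37.8% with at least 1000 genes, 36.1% and 38.6% with at most 10% mitochondrial UMIs, 34.6% and 37.3% at resolution 0.5, and 32.3% and 33.5% with list genes kept. The heterozygote corneal share was 30.1% with centring and 29.9% without cell-cycle-linked genes. The wild-type limbal share was 17.4% with at most 10% mitochondrial UMIs and 15.9% without doublet removal, and the heterozygote one 13.8% with at least 1000 genes and 24.9% without cell-cycle-linked genes.

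Ratios of single genes in the limbal comparison were unsteady: 768 values lay outside the counting interval of the value in the report, 1006 lay within it and 6 turned direction, and the cause was not tested. Only genes whose counting interval in the report's grouping left out 0 are counted as turned, and others with intervals spanning 0 also changed sign, in both libraries. In wild-type cells Nr4a1 had -0.37 with at least 1000 genes, -0.023 with at most 10% mitochondrial UMIs and -0.20 without doublet removal, where Klf2 had -0.11. With list genes kept, Asns had -0.11 and Nuak2 0.52, also in wild-type cells. In heterozygote cells Nr4a1 stayed between 1.10 and 2.17 and Klf2 between 0.50 and 1.39.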

Other observations

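The genes, clusters and ratios in this part were chosen after their values were seen. Within limbal basal-like cells (clusters 12, 17 and 23 with 86, 77 and 20 wild-type and 191, 83 and 16 heterozygote cells) ratios between the libraries were ranked for genes with a mean of at least 100 CPM there and a lower level outside the epithelium. Slurp1, a secreted Ly6 family protein, had 234 CPM in the wild-type and 532 CPM in the heterozygote library, a log2 ratio of 1.19 (1.06 to 1.31), against -0.04 in corneal cells. S100a9 (1.05), the water channel Aqp5 (0.94), Wfdc18 (0.83), Lypd2 (0.83), Wnt4 (0.62) and Krt12 (0.58) were higher as well. The limit on the level outside the epithelium does not remove free corneal RNA. Krt12 was also higher in heterozygote stromal cells, at 1228 CPM against 836 CPM. It had 6692 CPM in limbal cluster 12 and 1929 CPM in cluster 17, over which the libraries divided differently. Ceacam1 (-0.86), the retinal dehydrogenase Aldh1a3 (-0.75), Cbr2 (-0.72), Krt13 (-0.68), Calcb (-0.65) and the tissue factor gene F3 (-0.58) were lower. In corneal cells Ceacam1, Calcb and Aldh1a3 went the other way, at 0.93, 0.91 and 0.38. Among cholesterol synthesis genes of limbal cells Fdps (1.11) and Cyp51 (1.09) had the largest ratios.

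Pax6, Socs3 and Txnip were concentrated in a few epithelial clusters. In corneal clusters 5 and 18 Pax6 was counted at 500.1 and 621 CPM, against 37.1 CPM in cluster 1, 80.8 in cluster 2, 64.4 in cluster 6 and 89.4 in cluster 7. Socs3 had 384 and 351 CPM and Txnip 240 and 308 CPM in clusters 5 and 18. Cluster 5 held 9.83% of wild-type and 5.30% of heterozygote cells, and cluster 18 2.84% and 1.497%. Limbal cluster 23 had Pax6 at 344.5 CPM and Socs3 at 709 CPM.

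Gpha2 was not limited to limbal cells. It was counted at 550.4 CPM in wild-type and 524 CPM in heterozygote stromal cells and at 1703 and 1544 CPM in corneal endothelium-like cells. After thinning to 4000 UMIs, 36.9% and 37.4% of stromal cells had a Gpha2 UMI (58.1% and 49.6% before thinning), against 17.5% and 18.3% of corneal cells, 4.90% and 4.90% of superficial-like cells and 170 of 183 and 261 of 290 limbal cells. There were 6.69 and 3.12 Gpha2 UMIs per Krt15 UMI in stromal cells and 39.3 and 17.98 in corneal endothelium-like cells, against 0.454 and 0.527 in limbal cells. Stromal cells with at least 3 Gpha2 UMIs (155 and 317 cells) had Krt14 at 189 and 206 CPM, and stromal cells without any (208 and 586 cells) had 151 and 199 CPM. Kera, a keratocyte proteoglycan, had 4740 and 4328 CPM in the former and 3694 and 3290 CPM in the latter.

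An unnamed stromal cluster, cluster 20, held 10 wild-type and 105 heterozygote cells and may belong to that library more than to a cell type. Chil1, a chitinase-like protein, had 5001 CPM and Saa3, an acute phase protein, 234 CPM in it, and S100a4 and Timp1 were among its leading genes. With the unnamed stromal clusters added to the stromal class, the log2 ratio of Igfbp5 was -0.85 and that of Apoe 0.70.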
